A study of Homo sapiens with 12 samples.

How the data were processed

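RNA sequencing was done on Caco-2 cells, an established human colorectal adenocarcinoma line that is widely used as a model of the intestinal epithelium. The labels give 12 samples in 4 groups of 3: untreated control, sodium hydrosulfide (NaHS), bacterial lipopolysaccharide (LPS), and LPS with NaHS. NaHS is a salt that releases hydrogen sulfide in water. LPS was intended as the inflammatory condition. No dose or exposure time is given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate cultures, so every p-value below measures only the spread between these samples, which may be technical.

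Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with an Illumina mRNA sample preparation kit, and sequencing was paired-end. Reads were aligned with HISAT, per the submitters' processing notes, which give no version. The deposited gene table holds FPKM (fragments per kilobase of transcript per 1000000 mapped fragments) for 30992 loci, of which 9242 carry an Ensembl identifier and 21750 an assembled one. Of these loci, 500 had no gene name and 1501 had more than 1, so that neighbouring or overlapping genes share a single value. The deposited isoform table holds FPKM and read coverage for 154478 isoforms, 135325 of them annotated and 19153 assembled without a match. Genome build and annotation are not given in the sources used here. Coordinates and strand of 133247 of the 135161 annotated isoforms found in the GENCODE release 29 annotation of GRCh38 were identical to it, which is 98.6%, and coordinates are printed as deposited. Strand use in counting is not given either, so that reads of overlapping or antisense genes cannot be told apart. How the authors summarised isoforms to genes is also not given. For 6198 of 6860 loci with 1 isoform above 0 in the first library, 90.3%, the gene value equalled the isoform value within 0.1 percent.

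Depth was taken from the isoform table, in which the deposited coverage divided by FPKM is a constant in each library and equals the aligned gigabases. It ran from 5.62 to 7.63 gigabases per library. Counts of reads per gene are not in these units, so no counting interval is given. Precision was taken from the spread between the 3 libraries of a group. An exact 0 in these tables can be a failed estimate rather than absent RNA, so a locus at 0 is described as listed at 0.

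Values were analysed as log2(FPKM + 1), and every log2 fold change is on that scale, which understates changes of low genes. Genes with a mean of at least 1 FPKM over the 12 libraries were tested (10431 genes). All 12 libraries entered a single linear model with 4 group means, fitted with limma 3.58.1 in R 4.3.3 with moderated variances and a mean-variance trend. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, with a threshold of 0.05. The 5 comparisons were NaHS with control, LPS with control, LPS+NaHS with LPS, LPS+NaHS with control, and the interaction, which is the NaHS effect with LPS minus the NaHS effect without it. The same model was fitted to 25730 isoforms. No count model was used because the values are not counts.

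For gene groups, 28 lists of genes were tested with limma's camera, which asks whether members rank higher or lower than other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists within a comparison. Lists with fewer than 5 measured members (2 of them) were not tested. A second camera test used a correlation estimated from the data. Loci that join a listed gene with an unlisted one were left out of the lists. The lists were NRF2 antioxidant targets, hydrogen sulfide production and oxidation, ATF4 amino acid response, endoplasmic reticulum chaperones and unfolded protein response, cytosolic heat shock response, NF-kB targets and inflammatory cytokines, LPS sensing and TLR signalling, interferon-stimulated genes, antigen presentation, tight and adherens junctions, enterocyte differentiation and brush border, goblet and other secretory lineage markers, Wnt target genes, mitotic cell cycle, DNA replication, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, hypoxia and glycolysis, cholesterol biosynthesis, fatty acid oxidation and PPAR targets, p53 targets and apoptosis, metallothioneins and metal response, immediate early genes, aryl hydrocarbon receptor and xenobiotic metabolism, TGF-beta response and extracellular matrix, cytosolic ribosomal proteins, leukocyte and stromal markers as signs of other cell types, and replication-dependent histones with nuclear-retained RNAs as signs of RNA quality.

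Groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined. By that rule, each comparison names up to 8 genes per direction (4 for the interaction) with the largest log2 fold change among genes that passed, had a symbol, reached 2 FPKM in the higher group and had no overlap between the 3 values of each group, a condition dropped for the interaction. Where fewer than 4 passed in a direction, genes of smallest unadjusted p were added up to 4 and are said not to pass. For each described list, up to 4 members of smallest p are named. HMOX1, SQOR, CXCL8, NFKBIA, TLR4, OCLN, TJP1 and CLDN1 are reported whatever they did. At most 3 isoforms per comparison are named, those of smallest p in genes that did not pass. Some list members and isoforms that the rule picks are left out of the text, while counts and list tests include them.

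The model was tested on simulated data with 200 changed genes per comparison, in fits on 10431 genes. At a log2 change of 1 it recovered 68% for NaHS against control, 80% for LPS against control, 82% for LPS+NaHS against LPS, 68% for LPS+NaHS against control and 56% for the interaction. At 0.5 the shares were 22%, 30%, 34%, 30% and 2% in the same order. The same fits called 5, 7, 12, 6 and 6 unchanged genes. With 25730 isoforms and a log2 change of 2, recovery was 48%, 52%, 66%, 48% and 6%. Noise was drawn independently for each gene and library, so these simulations held no correlation between genes and no library trend with GC content. Recovery and false calls in the real libraries may therefore differ from these values. An adjusted p under 0.05 also becomes easier to reach as more genes change. The simulations changed 200 genes, whereas 2 to 26 genes passed in the real comparisons, so recovery there may be lower.

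Alternatives were a pseudocount of 0.1 or 0.5, no filter or a mean of at least 5 FPKM, 3 other scalings of the libraries (to a sum of 1000000, by median of ratios, and by quantiles), sums of isoform FPKM as gene values, limma without the trend, limma with sample weights, fits on only the groups compared, the replicate number as a block, the estimated inter-gene correlation, and leaving out each library in turn. Chosen after seeing the data were a correction of each library's trend with GC content in 20 bins, dropping the library of each group least similar to the others, and summing isoforms per gene symbol. Genes of lowest and highest GC content are the outer 2 of 4 equal groups. GC content was taken from the GENCODE release 29 transcript sequences for 9051 of the 10431 genes, or 86.8%. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.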

Results

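Polyadenylated RNA of Caco-2 cells was profiled in 12 libraries, 3 from each of 4 groups: control, NaHS, LPS and LPS+NaHS. The stated purpose was to see how a hydrogen sulfide donor alters gene expression of these intestinal epithelial cells in the normal state and under inflammation. Aligned sequence ran from 5.62 gigabases in LPS 3 to 7.63 gigabases in NaHS 1. Between 10242 and 10638 loci reached 1 FPKM in a library, and the 10 most abundant loci held 8.32% to 10.2% of the summed FPKM. Correlations of log2 values between libraries of a group were 0.934 to 0.950 in control, 0.943 to 0.950 in NaHS, 0.948 to 0.956 in LPS and 0.918 to 0.947 in LPS+NaHS. Libraries of different groups correlated at 0.912 to 0.955, a range that covers most of those within groups. The first principal component held 21.3% of the variance and did not part the groups. Along it, control 2 (22.4), LPS+NaHS 2 (22.5) and NaHS 1 (20.7) lay opposite LPS+NaHS 1 (-28.1) and LPS 2 (-20.3). Genes of lowest GC content deviated from their means by a median log2 of 0.26 in control 2, 0.28 in NaHS 1 and 0.22 in LPS+NaHS 2, and by -0.29 in LPS+NaHS 1 and -0.20 in LPS 2.

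**Figure D1:**
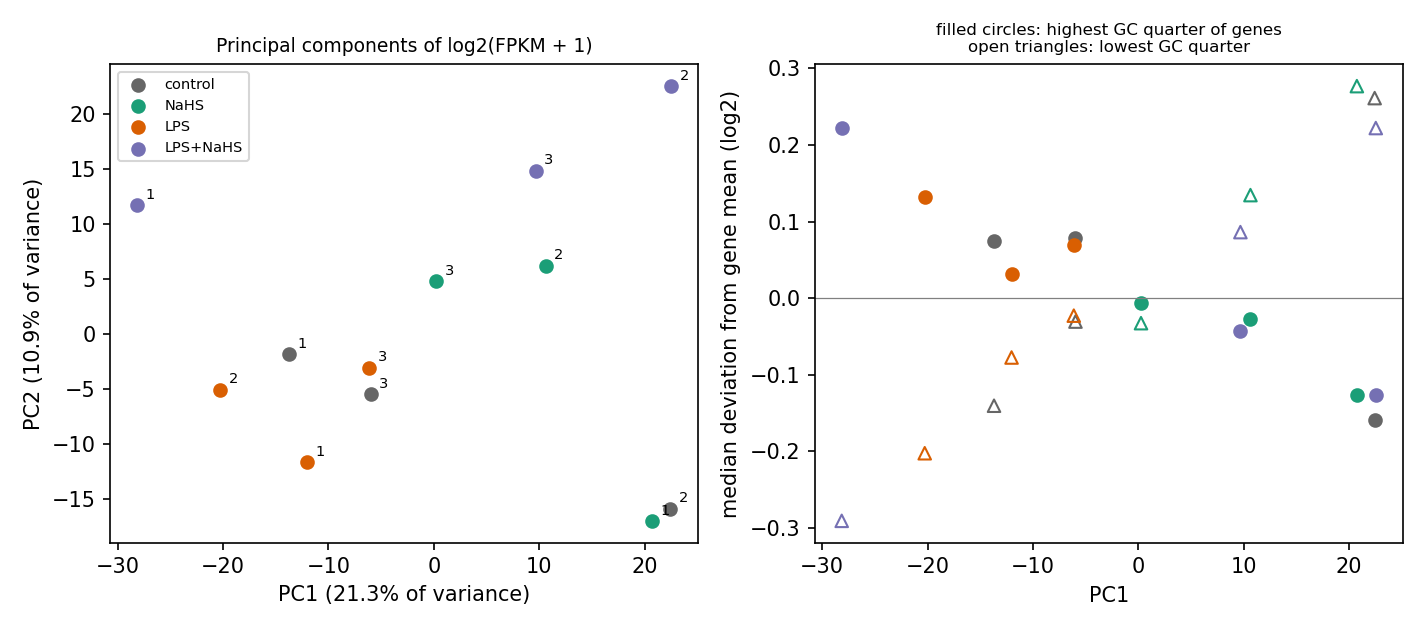
The left panel places the 12 libraries on the first (21.3% of variance) and second (10.9%) principal components of log2(FPKM + 1), coloured by group and numbered by replicate. The right panel plots, against the first component, the median log2 deviation from the gene mean of genes of highest (filled circles) and lowest (open triangles) GC content, and the latter runs from -0.29 in LPS+NaHS 1 to 0.28 in NaHS 1.

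Few genes passed with NaHS in resting cells. MCFD2, a partner of the cargo receptor that carries coagulation factors out of the endoplasmic reticulum, rose from 7.21 ± 0.884 FPKM in control to 28.2 ± 2.48 with NaHS (SD, n = 3), a log2 fold change of 1.83 ± 0.13 (SE; adjusted p = 0.000592). TMEM167A, a Golgi membrane protein of the secretory pathway, fell from 12.7 ± 2.35 to 2.20 ± 0.155 FPKM (log2 -2.09 ± 0.18, adjusted p = 0.00152). ITIH2 and KNG1 fell too. ITIH2, a heavy chain of the inter-alpha-trypsin inhibitor, went from 29 ± 2.38 to 12.9 ± 1.85 FPKM (log2 -1.12 ± 0.14, adjusted p = 0.0216), and KNG1, the kininogen from which bradykinin is cut, from 7.91 ± 0.280 to 3.23 ± 0.726 FPKM (log2 -1.09 ± 0.13, adjusted p = 0.0216). The locus of MCFD2 spans chromosome 2 from 46901870 to 46941855. TMEM167A spans chromosome 5 from 83052846 to 83077863, ITIH2 chromosome 10 from 7703269 to 7749520 and KNG1 chromosome 3 from 186717276 to 186743954.

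Several genes lay just outside the threshold. AFP, the alpha-fetoprotein gene, measured 3.22 ± 0.258 FPKM in control and 1.42 ± 0.238 with NaHS (log2 -0.80, adjusted p = 0.0546). SP5, a transcription factor that responds to Wnt signals, measured 1.11 ± 0.2 and 6.52 ± 1.10 FPKM (log2 1.83, adjusted p = 0.0945). PTRF, which encodes the caveolar coat protein cavin-1, measured 0.750 ± 0.137 and 25.1 ± 2.36 FPKM (log2 3.90, adjusted p = 0.0709), and was also among the 217 loci whose values fell into 2 separate levels. The spread in these tests was pooled over all 4 groups. It took in SP5 at 3.12 ± 2.27 FPKM with LPS and PTRF at 20.2 ± 15.6 FPKM with LPS+NaHS. A locus that joins POPDC2 with COX17, a copper chaperone, measured 2.00 ± 0.145 and 3.99 ± 0.364 FPKM (log2 0.73, adjusted p = 0.0546), and its reads cannot be assigned to either gene.

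Of the 26 lists tested, 5 passed in this comparison. Enterocyte differentiation and brush border genes fell as a group, with 3 of 15 members above 0 and a median log2 fold change of -0.25 (camera adjusted p = 5.9e-05, and adjusted p = 0.0311 with an estimated correlation). No member passed over all genes tested, and 3 were lower when adjusted over the list alone: SI, the brush border sucrase-isomaltase (2.58 ± 0.715 and 1.03 ± 0.429 FPKM, log2 -0.82), CDHR5, a microvillar cadherin (4.99 ± 0.903 and 3.17 ± 0.197 FPKM, log2 -0.51), and VIL1, the villin of microvilli (92.9 ± 6.95 and 73.9 ± 2.73 FPKM, log2 -0.32). APOA1, an apolipoprotein of enterocytes, measured 203 ± 95.2 and 105 ± 10.5 FPKM and did not pass either way. Interferon-stimulated genes also fell as a group, with 2 of 13 above 0 and a median of -0.33 (adjusted p = 5.9e-05, but adjusted p = 0.0614 with an estimated correlation). None of them passed over all genes and 4 were lower when adjusted over the list alone. Among these were OAS1 (11.4 ± 1.90 and 7.83 ± 1.05 FPKM), IFI6 (14.4 ± 1.33 and 8.25 ± 2.24) and IRF7 (5.77 ± 1.24 and 3.94 ± 0.580).

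NRF2 antioxidant targets rose as a group, with 13 of 16 above 0 and a median of 0.16 (adjusted p = 0.00185, but adjusted p = 0.267 with an estimated correlation). No NRF2 target passed over all genes, and 3 were higher when adjusted over the list alone. Among them were AKR1C1, an aldo-keto reductase (9.26 ± 1.33 and 17.7 ± 1.94 FPKM, log2 0.87), and ME1, the NADPH-forming malic enzyme (26.2 ± 4.57 and 43.5 ± 3.80, log2 0.72). The thioredoxin reductase gene TXNRD1 measured 8.50 ± 1.22 and 14.2 ± 1.18 FPKM and did not pass. Mitotic cell cycle genes (16 of 19 above 0, median 0.17, among them CCNB1, CCNB2, UBE2C and BUB1) and fatty acid oxidation and PPAR targets (2 of 14 above 0, median -0.07, among them SLC25A20, CREB3L3, HADHB and ACADS) each passed at an adjusted p of 0.0477. Neither held, at adjusted p = 0.539 with an estimated correlation for the mitotic list and adjusted p = 0.252 with an estimated correlation for fatty acid oxidation, and no member of either passed over all genes or when adjusted over the list alone.

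In all, 4 of 10431 genes passed with NaHS, 1 higher and 3 lower, and 494 had an unadjusted p under 0.05 where chance gives 522. With scaling to a fixed sum, which also let 15380 genes through the filter, 2 genes passed, 1 higher and 1 lower. The balance turned in fits on only the groups compared (10 higher and 3 lower) and without control 2 (6 higher and 2 lower). Each of these fits called 2 of the 4 genes. Larger counts came from sample weights, whose iteration did not converge (73, of which 35 were higher and 38 lower). Dropping the least similar libraries gave 21, of which 2 were among the 4, and the GC correction 12, of which 3 were. MCFD2 and TMEM167A passed under each of 14 alternatives and with any single library left out, whereas ITIH2 passed under 9 of 14 and KNG1 under 6 of 13. With a library left out, ITIH2 had an adjusted p of 0.0801 without control 1, 0.0538 without control 2, 0.0538 without NaHS 3, and KNG1 of 0.0801 without control 1, 0.0535 without control 2, 0.0721 without control 3, 0.0614 without NaHS 1. The NRF2 list had 0.223 without control 2, the mitotic list 0.305 without control 1, 0.0599 without control 2, 0.218 without NaHS 1, 0.0995 without NaHS 2, and the fatty acid oxidation list 0.198 without control 2, 0.0998 without control 3, 0.0837 without NaHS 1, 0.223 without NaHS 2. MCFD2 and TMEM167A were among 217 loci whose values fell into 2 separate levels across the libraries. Values of the 3 NaHS and 3 control libraries did not overlap for 1119 genes, 10.7% where chance gives 10%. The fold changes correlated with GC content at r = -0.190 across genes, and the histone and nuclear-retained RNA list had a median of -0.47 (adjusted p = 0.360). At the isoform level 6 passed, 2 higher and 4 lower, with 1381 under an unadjusted p of 0.05. The annotated RPL7 isoform ENST00000396467 (chromosome 8, 73290284 to 73293633, 6 exons) rose from 0.389 ± 0.393 to 13.6 ± 0.409 FPKM (adjusted p = 0.000606). An unannotated GRB7 isoform (chromosome 17, 39737353 to 39747289) measured 4.82, 6.28 and 3.62 FPKM in the control libraries and was listed at 0 in the other 9 (adjusted p = 0.00693). The RNF157 isoform ENST00000319945 fell from 7.46 ± 2.31 to 0.865 ± 0.334 FPKM (adjusted p = 0.0279). None of these 3 genes passed at the gene level.

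Between control and LPS, 2 genes passed, MCFD2 and PITHD1. MCFD2, a locus with 2 separate levels, rose to 23.8 ± 1.51 FPKM from 7.21 ± 0.884 in control (log2 1.6 ± 0.13, adjusted p = 0.00122). The same control libraries enter its rise with NaHS, so these rises are not independent. PITHD1 (chromosome 1, 23778369 to 23788366), which encodes a protein with a thioredoxin-family interaction domain, fell from 8.81 ± 0.336 to 3.75 ± 0.295 FPKM (log2 -1.05 ± 0.09, adjusted p = 0.00122). The merged locus of HSPA1A and HSPA1B, near-identical genes for the stress-inducible chaperone HSP70, measured 106 ± 5.84 FPKM in control and 37.5 ± 11.4 with LPS and did not pass (log2 -1.52 ± 0.20, adjusted p = 0.0620). PTRF, with 2 separate levels as above, measured 0.750 ± 0.137 and 31.5 ± 2.80 FPKM (log2 4.22, adjusted p = 0.0632). Also short of the threshold were RP11-1029J19.5 (0.884 ± 0.289 and 2.02 ± 0.118 FPKM, adjusted p = 0.306), the secreted ribonuclease gene RNASE1 (3.51 ± 0.342 and 6.03 ± 0.792, adjusted p = 0.627), the membrane protein gene TM4SF1 (26.7 ± 1.85 and 18.2 ± 1.46, adjusted p = 0.627) and the semaphorin and VEGF co-receptor NRP1 (4.21 ± 0.181 and 2.34 ± 0.107, adjusted p = 0.713).

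Genes of hypoxia and glycolysis rose together after LPS, with 16 of 18 above 0 and a median log2 fold change of 0.33 (camera adjusted p = 3.48e-09, and adjusted p = 0.0134 with an estimated correlation). None passed over all genes, and 5 were higher when adjusted over the list alone. Among them were the hypoxia-induced NDRG1 (71.2 ± 27.0 and 130 ± 0.184 FPKM), the glycolytic enzymes ENO1 (616 ± 61.2 and 797 ± 24.9) and TPI1 (527 ± 14.3 and 801 ± 171), and BNIP3, a mitophagy receptor (9.5 ± 0.334 and 13.9 ± 1.70). The cytosolic heat shock list fell, with 2 of 12 above 0 and a median of -0.23 (adjusted p = 0.0168, but adjusted p = 0.469 with an estimated correlation), and only the HSPA1A and HSPA1B locus was lower when adjusted over the list alone. DNAJA1 (74.4 ± 13.8 and 51.2 ± 6.17 FPKM), HSPA8 (396 ± 24.5 and 318 ± 14.4) and HSPH1 (11.5 ± 2.96 and 7.43 ± 1.26), all chaperone genes, were the next members by p. Cytosolic ribosomal protein genes rose slightly, with 18 of 22 above 0 and a median of 0.09 (adjusted p = 0.0168, but adjusted p = 0.469 with an estimated correlation). No ribosomal gene passed, whether over all genes or adjusted over the list alone. The members of smallest p were RPS3 (log2 0.37), RPS19 (0.25), RPL8 (0.30) and RPLP0 (0.19). NF-kB targets and inflammatory cytokines did not pass, with 11 of 18 above 0, a median of 0.05, a mean of -0.05 and an adjusted p of 0.373.

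For LPS 2 of 10431 genes passed, 1 in each direction, and 431 had an unadjusted p under 0.05. The count was 4 without control 1, 6 without control 2 (5 higher and 1 lower), 6 without control 3, 9 without LPS 1 (3 higher and 6 lower) and 5 without LPS 2. No filter gave 8, sample weights 10, fits on only the groups compared 5, and dropping the least similar libraries 20 (13 higher and 7 lower). A pseudocount of 0.5, a mean of at least 5 FPKM, sums of isoforms and the GC correction gave 4 each. MCFD2 and PITHD1 passed under each of 14 alternatives and with any single library left out. The heat shock call ended without control 1 (adjusted p = 0.0571) and without control 2 (adjusted p = 0.102), and the ribosomal call without control 2 (adjusted p = 0.595) and without LPS 3 (adjusted p = 0.0751). The HSPA1A and HSPA1B locus passed with an adjusted p of 0.0127 without LPS 1, 0.0289 without LPS 3. Non-overlapping values were found for 1459 genes, 14% where chance gives 10%. The fold changes correlated with GC content at r = 0.256 across genes, and the histone and nuclear-retained RNA list had a median of -0.26 (adjusted p = 0.117), with RN7SL1, another locus with 2 separate levels, listed at 0 in the 3 LPS libraries. The low level of RN7SL1 held 7 libraries, which came from all 4 groups. Among 6 isoforms past the threshold, 3 were higher and 3 lower, with 1215 under an unadjusted p of 0.05. The unannotated GRB7 isoform was listed at 0 with LPS as well (adjusted p = 0.0202), against the same control libraries as with NaHS. The PCCB isoform ENST00000469217 fell from 2.25 ± 0.295 to 0.037 ± 0.0636 FPKM (adjusted p = 0.0436). The TMEM52 isoform ENST00000378602 was listed at 0 in control and measured 2.38, 3.87 and 3.91 FPKM in the LPS libraries (adjusted p = 0.0436).

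Among genes higher with LPS+NaHS than with LPS were AKR1C1, AKR1C2 and CYP1A1, while the list of aryl hydrocarbon receptor and xenobiotic genes did not pass (5 of 7 above 0, median 0.22, adjusted p = 0.0904, and adjusted p = 0.437 with an estimated correlation). AKR1C1 (chromosome 10, 4963253 to 4983283) rose from 7.46 ± 0.411 FPKM with LPS to 36.1 ± 8.17 with LPS+NaHS (log2 2.11 ± 0.16, adjusted p = 0.00025). Its neighbour AKR1C2 (chromosome 10, 4987400 to 5018031) rose from 9.07 ± 1.11 to 39.4 ± 16.1 FPKM (log2 1.94 ± 0.23, adjusted p = 0.0115). Both encode reductases of steroids and carbonyls and are near copies, so reads may be split wrongly between them. CYP1A1 (chromosome 15, 74719542 to 74725610), the classic aryl hydrocarbon receptor target, rose from 6.39 ± 0.981 to 16.7 ± 4.05 FPKM (log2 1.24 ± 0.16, adjusted p = 0.0131). The merged HSPA1A and HSPA1B locus (chromosome 6, 31815464 to 31830255) went from 37.5 ± 11.4 to 111 ± 13.1 FPKM (log2 1.58 ± 0.20, adjusted p = 0.0131). PITHD1 went from 3.75 ± 0.295 to 9.40 ± 0.622 FPKM (log2 1.13 ± 0.09, adjusted p = 0.000292). Control values were 106 ± 5.84 and 8.81 ± 0.336. The same LPS libraries enter the fall from control and this rise, so the fall and the rise are not independent. The fall of the HSPA1A and HSPA1B locus did not pass.

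TM4SF1 rose from 18.2 ± 1.46 to 32.8 ± 3.6 FPKM (adjusted p = 0.0120) and the joined POPDC2 and COX17 locus from 1.97 ± 0.0766 to 4.31 ± 0.643 FPKM (adjusted p = 0.0115). GSG2, the gene of the histone kinase haspin (chromosome 17, 3723903 to 3726699, 1 exon), measured 4.42, 4.72 and 4.17 FPKM in the LPS+NaHS libraries and was listed at 0 in the other 9 (adjusted p = 1.84e-07). GDF11 (chromosome 12, 55743280 to 55757278), a ligand of the TGF-beta family, fell from 4.05 ± 0.0930 to 0.624 ± 0.0801 FPKM (log2 -1.64 ± 0.08, adjusted p = 3.14e-06). GSG2 and GDF11 were also among the 217 loci with 2 separate levels. KNG1 fell from 6.27 ± 0.309 to 2.29 ± 0.422 FPKM (log2 -1.15 ± 0.13, adjusted p = 0.0104), the lipocalin gene APOD from 158 ± 11.7 to 102 ± 5.35 FPKM (adjusted p = 0.0233), and the sugar-amine kinase gene FN3KRP from 14.8 ± 1.69 to 6.92 ± 0.257 FPKM (adjusted p = 0.0489).

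**Figure D2:**
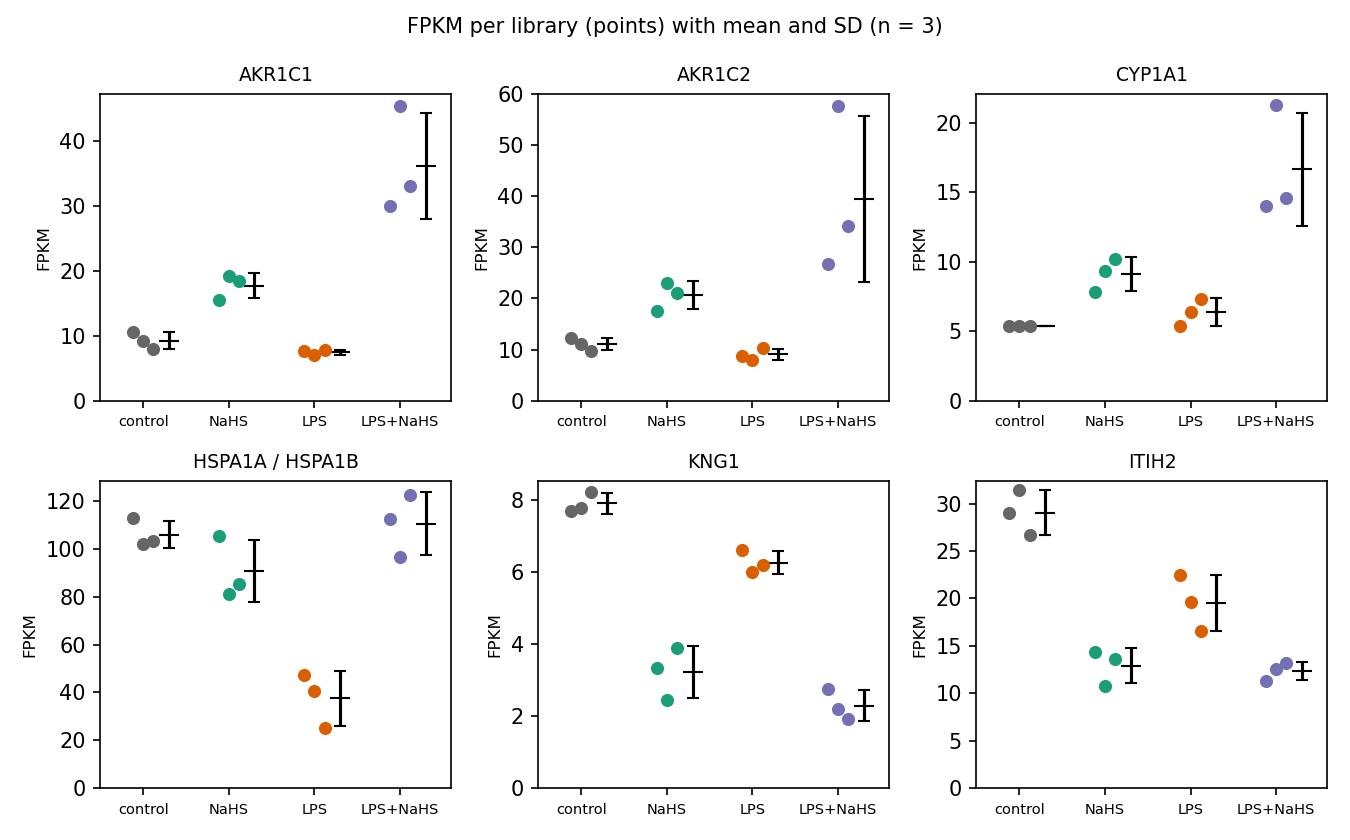
FPKM (vertical axis, from 0) of 6 loci in each library of the 4 groups (horizontal axis), as points, with the group mean and SD (n = 3) as black bars. AKR1C1, AKR1C2 and CYP1A1 were highest with LPS+NaHS, HSPA1A / HSPA1B was low with LPS alone, and KNG1 and ITIH2 were lower in both NaHS groups than in control.

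NRF2 antioxidant targets rose as a group, with 13 of 16 above 0 and a median log2 fold change of 0.30 (camera adjusted p = 3.26e-06, but adjusted p = 0.0987 with an estimated correlation). AKR1C1 alone passed over all genes. When adjusted over the list alone 6 members were higher, among them TXNRD1 (7.27 ± 0.839 and 18.9 ± 8.46 FPKM) and the quinone reductase gene NQO1 (137 ± 22.5 and 199 ± 39.7). Immediate early genes rose, with 12 of 13 above 0 and a median of 0.29 (adjusted p = 0.000592, but adjusted p = 0.0665 with an estimated correlation). None passed over all genes and 3 were higher when adjusted over the list alone: DUSP6, a phosphatase of ERK (5.12 ± 1.11 and 9.66 ± 2.10 FPKM), and the transcription factors JUN (2.02 ± 1.88 and 6.61 ± 1.49) and MYC (10.5 ± 1.32 and 18.1 ± 2.31). FOS measured 3.22 ± 1.27 and 4.97 ± 1.19 FPKM and did not pass. JUNB and IER2, on the same list, were among the 217 loci with 2 separate levels.

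The heat shock list rose, with 10 of 12 above 0 and a median of 0.24 (adjusted p = 0.00128, but adjusted p = 0.248 with an estimated correlation). Only the HSPA1A and HSPA1B locus passed, both over all genes and when adjusted over the list alone, and DNAJA1 (51.2 ± 6.17 and 85.7 ± 33.9 FPKM), HSPA8 (318 ± 14.4 and 429 ± 126) and HSPH1 (7.43 ± 1.26 and 13.1 ± 6.39) did not. NF-kB targets rose, with 14 of 18 above 0 and a median of 0.24 (adjusted p = 0.00504, but adjusted p = 0.0861 with an estimated correlation). No member of that list passed, over all genes or adjusted over the list alone, and the smallest p belonged to the chemokine gene CCL20 (6.23 ± 1.47 and 10.7 ± 1.53 FPKM), the inhibitor NFKBIA (20.8 ± 1.79 and 29.3 ± 6.30), the subunit RELB (3.19 ± 0.269 and 4.34 ± 0.844) and the chemokine gene CXCL1 (2.54 ± 1.70 and 4.69 ± 1.33). Goblet and other secretory markers rose, with 5 of 6 above 0 and a median of 0.21 (adjusted p = 0.0148, but adjusted p = 0.102 with an estimated correlation). None passed over all genes and 2 were higher when adjusted over the list alone, the lysozyme gene LYZ (4.86 ± 0.990 and 10.1 ± 3.61 FPKM) and the trefoil factor gene TFF1 (66.8 ± 3.69 and 92.2 ± 7.45). AGR2 and MUC13 had log2 fold changes of 0.22 and 0.19 and did not pass.

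Altogether 14 genes passed, 10 higher and 4 lower, with 860 under an unadjusted p of 0.05. Scaling by median of ratios gave 13, of which 11 were higher and 2 lower. Fits on only the groups compared gave 9, 5 higher and 4 lower, of which only 4 were among the 14. No filter gave 25, 14 higher and 11 lower, of which 13 were among the 14. With LPS+NaHS 1 left out, 142 genes passed, 69 higher and 73 lower, and without LPS 3 there were 9. Dropping the least similar library of each group gave 24, 9 higher and 15 lower, of which only 5 were among the 14. Also without LPS+NaHS 1, the NF-kB list (adjusted p = 0.230) and the goblet list (adjusted p = 0.0875) no longer passed. GSG2, AKR1C1, GDF11 and PITHD1 passed in every alternative that tested them and with any single library left out. The filter of at least 5 FPKM left GSG2 and GDF11 untested. FN3KRP passed under 5 of 14 alternatives and APOD under 8 of 14. Calls ended with a library left out for AKR1C2 (adjusted p = 0.0505 without LPS 2), the HSPA1A and HSPA1B locus (0.0704 without LPS+NaHS 3), CYP1A1 (0.0624 without LPS 1, 0.0613 without LPS 2) and the joined POPDC2 and COX17 locus (0.0517 without LPS 1, 0.0589 without LPS 3). The same held for TM4SF1 (0.0613 without LPS 2, 0.0589 without LPS 3, 0.0685 without LPS+NaHS 3), FN3KRP (0.0802 without LPS 1, 0.232 without LPS 2, 0.174 without LPS 3, 0.144 without LPS+NaHS 2, 0.148 without LPS+NaHS 3) and APOD (0.115 without LPS 1, 0.116 without LPS 2, 0.0589 without LPS 3, 0.0943 without LPS+NaHS 2, 0.0878 without LPS+NaHS 3). Non-overlapping values were found for 1200 genes, 11.5% where chance gives 10%. The fold changes correlated with GC content at r = -0.193 across genes, and the histone and nuclear-retained RNA list had a median of 0.51 (adjusted p = 0.173). At the isoform level 10 passed, 7 higher and 3 lower, with 1529 under an unadjusted p of 0.05. The UQCR10 isoform ENST00000401406 rose from 3.99 ± 0.578 to 21.3 ± 4.72 FPKM (adjusted p = 0.00196). The PMF1 isoform ENST00000368277 measured 42.6, 44.6 and 32.4 FPKM with LPS, and with LPS+NaHS was listed at 0 in 2 libraries and at 0.241 FPKM in the third (adjusted p = 0.00196).

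**Figure D3:**
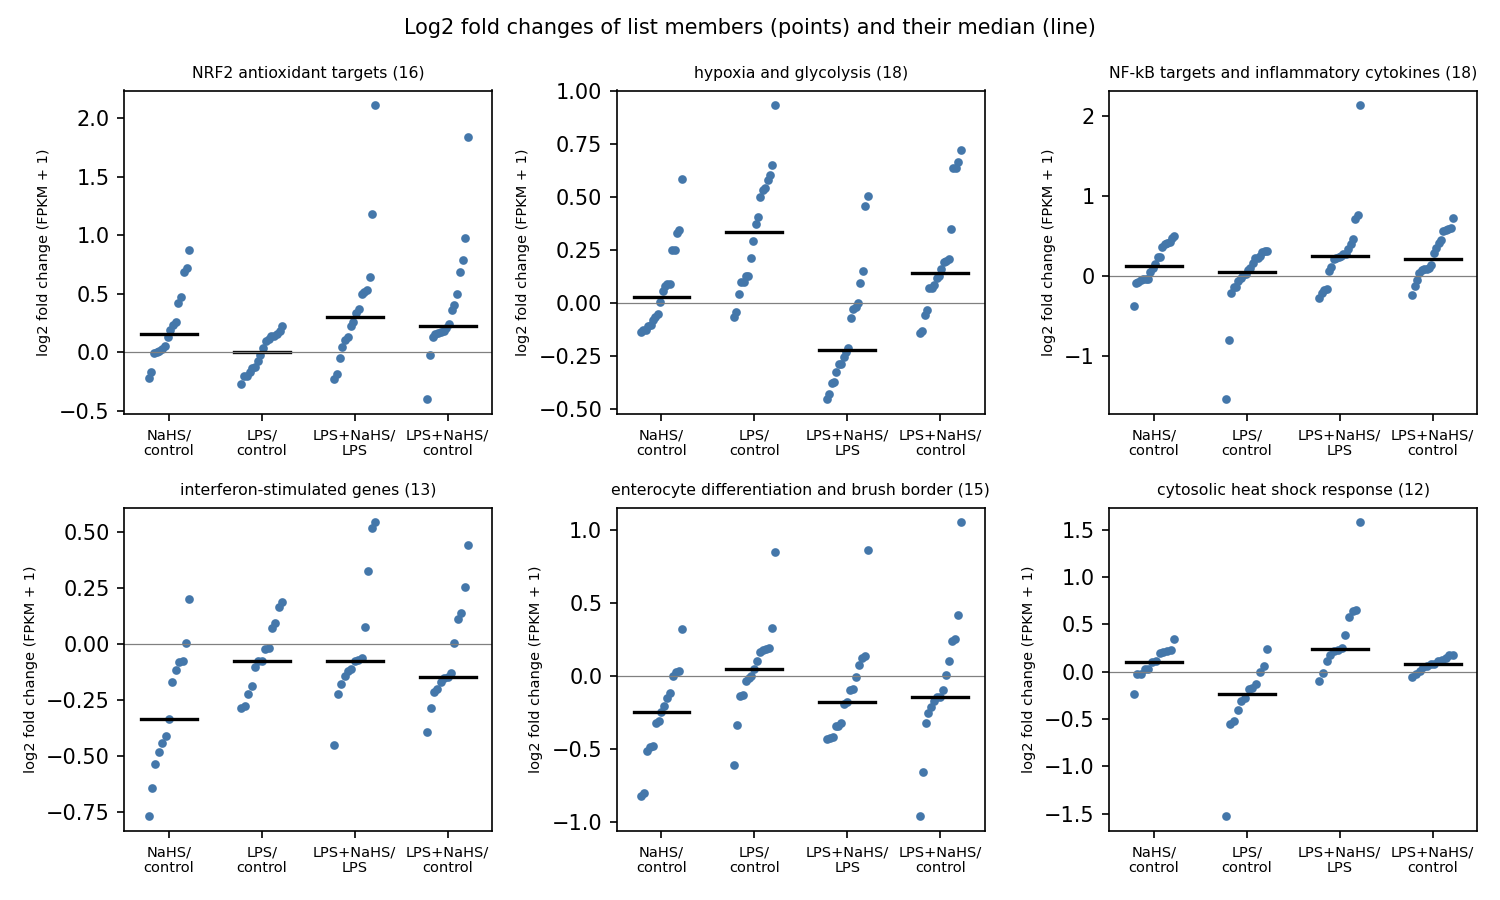
Log2 fold change of log2(FPKM + 1) (vertical axis) of each measured member of 6 gene lists (points) and the list median (line) in 4 comparisons (horizontal axis), with the number of members in brackets. The hypoxia and glycolysis median was 0.33 for LPS against control, and the NRF2 median was 0.30 for LPS+NaHS against LPS.

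Between control and LPS+NaHS, AKR1C1 rose from 9.26 ± 1.33 to 36.1 ± 8.17 FPKM (log2 1.84 ± 0.16, adjusted p = 0.00071), AKR1C2 from 11.1 ± 1.26 to 39.4 ± 16.1 FPKM (adjusted p = 0.0246) and CYP1A1 from 5.38 ± 0.0159 to 16.7 ± 4.05 FPKM (log2 1.45 ± 0.16, adjusted p = 0.00516). The joined AKR1B15 and AKR1B10 locus (chromosome 7, 134527515 to 134579875), also of aldo-keto reductases, rose from 0.998 ± 0.114 to 8.49 ± 6.25 FPKM (adjusted p = 0.0463). Lower genes included KNG1, from 7.91 ± 0.280 to 2.29 ± 0.422 FPKM (log2 -1.45 ± 0.13, adjusted p = 0.00124), ITIH2 from 29 ± 2.38 to 12.3 ± 0.995 FPKM (log2 -1.17 ± 0.14, adjusted p = 0.00625) and the fibrinogen chain gene FGB from 4.09 ± 0.517 to 1.34 ± 0.652 FPKM (adjusted p = 0.0359). A pair of serine palmitoyltransferase subunits, which start sphingolipid synthesis, fell as well, SPTSSB from 11.3 ± 1.88 to 4.03 ± 0.443 FPKM (adjusted p = 0.0235) and SPTLC3 from 8.69 ± 1.15 to 3.99 ± 0.393 FPKM (adjusted p = 0.0359).

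The laminin chain gene LAMA1 (chromosome 18, 6941744 to 7117814) fell from 21.5 ± 0.589 to 6.52 ± 2.83 FPKM (log2 -1.66 ± 0.25, adjusted p = 0.0344), and SCGN, a calcium-binding protein of endocrine cells, from 5.33 ± 0.815 to 2.68 ± 0.256 FPKM (adjusted p = 0.0285). GDF11 fell from 4.33 ± 0.208 to 0.624 ± 0.0801 FPKM (log2 -1.71 ± 0.08, adjusted p = 1.99e-06). MCFD2 rose to 26.9 ± 4.48 FPKM (log2 1.76 ± 0.13, adjusted p = 0.000298), SP5 (chromosome 2, 170715351 to 170718078) to 7.00 ± 0.646 from 1.11 ± 0.2 FPKM (adjusted p = 0.0344), and CD3EAP, a subunit of RNA polymerase I, to 3.63 ± 1.30 from 0.620 ± 0.494 FPKM (adjusted p = 0.0344). GSG2 passed as above (adjusted p = 1.84e-07).

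NRF2 targets rose as a group, with 14 of 16 above 0 and a median log2 fold change of 0.22 (camera adjusted p = 1.14e-09, and adjusted p = 0.0461 with an estimated correlation). AKR1C1 passed over all genes, and 4 were higher when adjusted over the list alone, among them ME1 (26.2 ± 4.57 and 42.8 ± 8.94 FPKM) and TXNRD1 (8.50 ± 1.22 and 18.9 ± 8.46). NF-kB targets rose, with 15 of 18 above 0 and a median of 0.21 (adjusted p = 0.000138, and adjusted p = 0.0369 with an estimated correlation). No NF-kB target passed over all genes and 4 were higher when adjusted over the list alone: RELB (2.53 ± 0.179 and 4.34 ± 0.844 FPKM), CCL20 (6.04 ± 0.349 and 10.7 ± 1.53), NFKBIA (19.4 ± 2.52 and 29.3 ± 6.30) and the cytokine gene IL32 (10.9 ± 1.73 and 15.1 ± 1.62). The hypoxia and glycolysis list rose, with 14 of 18 above 0 and a median of 0.14 (adjusted p = 0.00576, but adjusted p = 0.153 with an estimated correlation). Of its members none passed over all genes and 1 was higher when adjusted over the list alone, ANKRD37 (1.94 ± 0.0967 and 3.71 ± 0.758 FPKM). VEGFA, NDRG1 and ADM had log2 fold changes of 0.64, 0.72 and 0.64 and did not pass. Ribosomal protein genes rose slightly, with 19 of 22 above 0 and a median of 0.08 (adjusted p = 0.0442, but adjusted p = 0.581 with an estimated correlation). None of these passed over all genes or when adjusted over the list alone. RPS27A, RPL27, RPLP2 and RPL19 had log2 fold changes of 0.16, 0.15, 0.17 and 0.10.

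Here 26 genes passed, 13 in each direction, with 714 under an unadjusted p of 0.05. Of the 16 named, GSG2, AKR1C1, MCFD2, GDF11 and KNG1 passed in every alternative that tested them and with any single library left out. The filter of at least 5 FPKM left GSG2, GDF11 and KNG1 untested. With a library left out, calls ended for SP5 (adjusted p = 0.104 without control 1, 0.157 without control 2, 0.0972 without control 3, 0.0627 without LPS+NaHS 1, 0.0877 without LPS+NaHS 2, 0.124 without LPS+NaHS 3), SPTLC3 (0.106 without control 1, 0.157 without control 2, 0.0801 without control 3, 0.0614 without LPS+NaHS 1, 0.124 without LPS+NaHS 2, 0.0886 without LPS+NaHS 3) and FGB (0.0872 without control 1, 0.157 without control 2, 0.120 without control 3, 0.0652 without LPS+NaHS 1, 0.147 without LPS+NaHS 3). So did those of AKR1C2 (0.0589 without control 1, 0.0964 without control 2, 0.0801 without control 3, 0.0733 without LPS+NaHS 3), the AKR1B15 and AKR1B10 locus (0.135 without control 1, 0.157 without control 2, 0.158 without control 3, 0.118 without LPS+NaHS 3) and CD3EAP (0.112 without control 1, 0.157 without control 2, 0.0761 without LPS+NaHS 2, 0.0879 without LPS+NaHS 3). LAMA1 (0.106 without control 1, 0.156 without control 2, 0.107 without control 3, 0.0971 without LPS+NaHS 3), SCGN (0.0837 without control 1, 0.0964 without control 2, 0.104 without LPS+NaHS 3) and SPTSSB (0.0943 without control 2, 0.0564 without control 3, 0.0879 without LPS+NaHS 3) lost theirs too. Sample weights and leaving out LPS+NaHS 3 gave 12 genes each, control 1 left out gave 15 and control 2 left out 14. Fits on only the groups compared gave 13, of which 7 were among the 26, with the balance turned to 10 higher and 3 lower. Scaling to a fixed sum, with 15380 genes tested, gave 14. The GC correction gave 49 and leaving out LPS+NaHS 1 gave 42. Leaving out LPS+NaHS 1 ended the call of the hypoxia list (adjusted p = 0.176) and the ribosomal list (adjusted p = 0.589), as did leaving out LPS+NaHS 3 (adjusted p = 0.0722 and 0.131), and leaving out control 2 that of the ribosomal list (adjusted p = 0.713). Values did not overlap for 982 genes, 9.41% where chance gives 10%. Fold changes correlated with GC content at r = 0.05 across genes, and the histone and nuclear-retained RNA list had a median of -0.12 (adjusted p = 0.870). Among isoforms, 13 passed, 8 higher and 5 lower, with 1457 under an unadjusted p of 0.05. The UQCR10 isoform rose (4.22 ± 0.196 to 21.3 ± 4.72 FPKM, adjusted p = 0.00317). The GRB7 isoform was listed at 0 with LPS+NaHS (adjusted p = 0.00346), again against the same control libraries.

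Whether NaHS acted differently with and without LPS was tested by the interaction, and 5 genes passed, 3 higher and 2 lower, with 371 under an unadjusted p of 0.05. There were 8 without control 2 (3 higher and 5 lower) and 8 without NaHS 2 or LPS 1 (5 higher and 3 lower). No filter gave 12 (6 in each direction), a mean of at least 5 FPKM 3, and dropping the least similar libraries 21 (7 higher and 14 lower). TMEM167A had an interaction of log2 2.32 ± 0.25 (adjusted p = 0.00977): it measured 12.7 ± 2.35 FPKM in control and 2.20 ± 0.155 with NaHS, and 10.7 ± 0.863 FPKM with LPS and 13 ± 3.46 with LPS+NaHS. MCFD2 had an interaction of -1.67 ± 0.19 (adjusted p = 0.00977), being already at 23.8 ± 1.51 FPKM with LPS. It was low only in the control libraries (7.21 ± 0.884 FPKM). These enter its interaction and its calls for NaHS, LPS and LPS+NaHS against control, so those calls are not independent. PITHD1 had 1.03 ± 0.12 (adjusted p = 0.0148), GDF11 -1.6 ± 0.11 (adjusted p = 0.000132) and GSG2 2.44 ± 0.11 (adjusted p = 6.21e-06), which rests on 9 libraries listed at 0. Not passing were HSPA1A and HSPA1B (log2 1.81, adjusted p = 0.119), RNASE1 (-1.12, adjusted p = 0.119) and PTRF (-4.97, adjusted p = 0.148), the last, a locus with 2 separate levels, measuring 34.2, 3.38 and 22.9 FPKM in the LPS+NaHS libraries. PITHD1 no longer passed with an adjusted p of 0.0593 without control 3, 0.0614 without LPS 3, 0.0672 without LPS+NaHS 3, while the HSPA1A and HSPA1B locus passed with 0.0399 without LPS 1, 0.0441 without LPS 3, and PTRF with 0.0450 without LPS+NaHS 1, 7.81e-05 without LPS+NaHS 2.

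**Figure D4:**
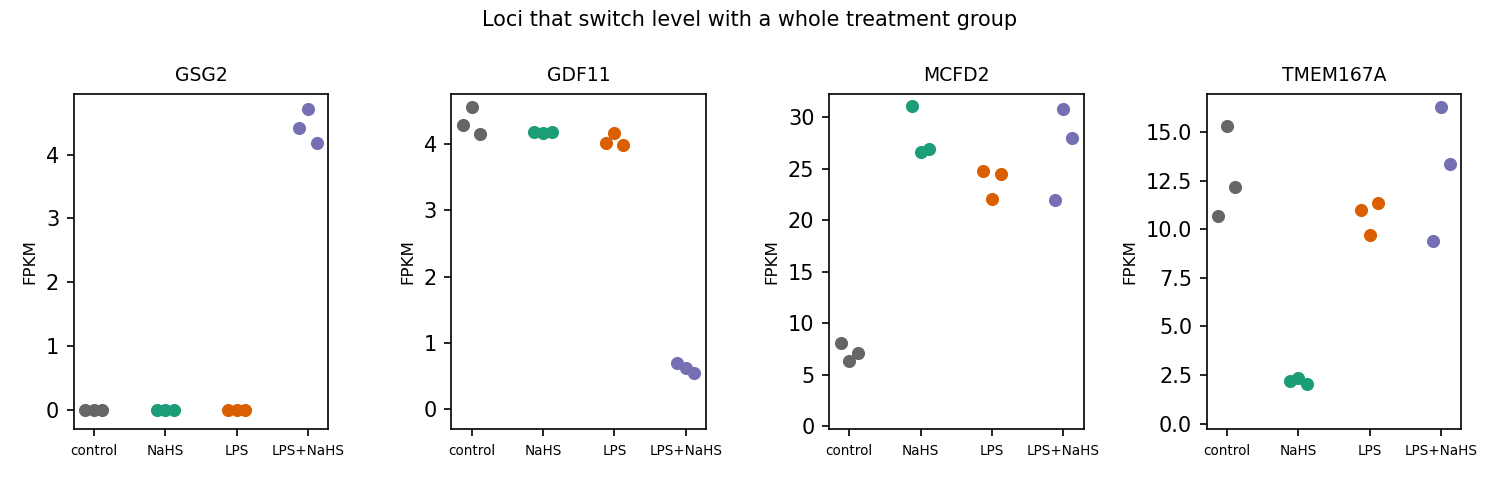
FPKM (vertical axis) of 4 loci in each library (points) of the 4 groups (horizontal axis). GSG2 was listed at 0 outside LPS+NaHS, GDF11 was low with LPS+NaHS, MCFD2 low in control and TMEM167A low with NaHS alone, with no overlap between the levels.

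Of the lists, 10 passed for the interaction and none held with an estimated correlation. Among the 7 lists with higher terms, goblet and other secretory markers had 6 of 6 above 0 and a median of 0.38 (adjusted p = 0.00869, but adjusted p = 0.162 with an estimated correlation), led by TFF1, LYZ, TFF3 and AGR2. Interferon-stimulated genes had 10 of 13 above 0 and a median of 0.27 (adjusted p = 0.0184, but adjusted p = 0.216 with an estimated correlation), led by IFI27 (log2 0.88) and IFI6 (1.09), with IFIT2 at -0.65 and OAS1 at 0.41. Immediate early genes had 11 of 13 above 0 and a median of 0.29 (adjusted p = 0.0184, but adjusted p = 0.213 with an estimated correlation), led by JUN (1.37), KLF6, DUSP6 and EGR1. NRF2 targets had 12 of 16 above 0 and a median of 0.08 (adjusted p = 0.0200, but adjusted p = 0.315 with an estimated correlation), led by AKR1C1 (1.24), FTH1, ABCC2 and TXNRD1. Heat shock genes had 10 of 12 above 0 and a median of 0.14 (adjusted p = 0.0200, but adjusted p = 0.337 with an estimated correlation), led by HSPA1A and HSPA1B (1.81), HSPA8, BAG3 and HSPH1. Aryl hydrocarbon receptor and xenobiotic genes had 6 of 7 above 0 and a median of 0.32 (adjusted p = 0.0158, but adjusted p = 0.281 with an estimated correlation), led by GSTA1 (0.65), CYP1A1 (0.58), GSTA2 and CYP3A5.

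Lower interaction terms were found for 3 lists. Hypoxia and glycolysis had 2 of 18 above 0 and a median of -0.17 (adjusted p = 0.0184, but adjusted p = 0.216 with an estimated correlation), led by BNIP3 (-0.68), NDRG1, GAPDH and PGK1. Cholesterol biosynthesis had 2 of 19 above 0 and a median of -0.17 (adjusted p = 0.0184, but adjusted p = 0.216 with an estimated correlation), led by MSMO1 (-1.20), DHCR7, SQLE and LSS. Mitotic genes had 3 of 19 above 0 and a median of -0.15 (adjusted p = 0.0200, but adjusted p = 0.337 with an estimated correlation), with CCNB2, AURKB and UBE2C below 0 and TPX2 above it among the members of smallest p. The histone and nuclear-retained RNA list, a sign of RNA quality, moved with these lists: it had 5 of 6 above 0 and a median of 0.70 (adjusted p = 0.0299, but adjusted p = 0.281 with an estimated correlation), led by HIST1H2BK (1.19), MALAT1, RN7SL1 and RPPH1. Over all genes tested no member of the 10 lists passed. Adjusted over the list alone, 1 member each was higher for the NRF2 (AKR1C1), heat shock (HSPA1A and HSPA1B), interferon (IFI27) and histone (HIST1H2BK) lists and 0 for the other 6. Only the goblet list passed in each of the 12 fits with a library left out. Among isoforms, 3 passed, 1 higher and 2 lower, with 1170 under an unadjusted p of 0.05, among them the RPL7 isoform (log2 -3.52, adjusted p = 0.00663).

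With a library left out, interaction calls of the other 9 lists ended as follows. The NRF2 list had an adjusted p of 0.161 without control 1, 0.110 without NaHS 1, 0.0542 without LPS 1, 0.170 without LPS+NaHS 2. For the heat shock list it was 0.162 without control 2, 0.0849 without NaHS 3, 0.298 without LPS+NaHS 2, 0.0587 without LPS+NaHS 3. For the interferon list it was 0.0550 without NaHS 2, 0.0566 without LPS 3, 0.0587 without LPS+NaHS 3. For the immediate early list it was 0.0780 without LPS 1, 0.0503 without LPS+NaHS 1, 0.0587 without LPS+NaHS 3. For the aryl hydrocarbon receptor list it was 0.0509 without control 2, 0.117 without LPS+NaHS 2. For the mitotic list it was 0.183 without control 1, 0.110 without NaHS 1, 0.199 without LPS+NaHS 1, 0.0860 without LPS+NaHS 3. For the hypoxia list it was 0.159 without LPS+NaHS 2. For the cholesterol list it was 0.159 without LPS+NaHS 2. For the histone list it was 0.358 without control 1, 0.0618 without NaHS 3, 0.0641 without LPS 1, 0.131 without LPS 3, 0.258 without LPS+NaHS 1, 0.0682 without LPS+NaHS 3.

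Across the 10431 genes, which are not independent replicates, the NaHS effects without and with LPS correlated at r = 0.149. These effects share no libraries, and 16 of 100 permutations of the labels within each pair of groups gave a value as large (permutation p = 0.160, highest other value 0.288). The LPS effect and the NaHS effect in LPS cells correlated at r = -0.510 with a covariance of -0.0481, where unchanged groups simulated with the same shared LPS libraries gave -0.501 and -0.0430. The NaHS and LPS effects against the same controls correlated at r = 0.357 with a covariance of 0.0317, where simulation gave 0.497 and 0.0429. A split of the 3 shared libraries would leave 1 of them on one side and was not made, so part or all of these values may come from shared libraries.

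Genes of prior interest did not pass in any comparison in which they were tested. HMOX1, the heme oxygenase gene and an NRF2 target, measured 4.95 ± 0.444 FPKM in control, 4.13 ± 0.646 with NaHS, 5.63 ± 0.0620 with LPS and 4.88 ± 0.918 with LPS+NaHS. NFKBIA had its largest log2 fold change, 0.56 ± 0.15, between LPS+NaHS and control (adjusted p = 0.338). The tight junction genes OCLN (10.7 ± 4.77, 9.98 ± 2.89, 8.59 ± 2.11 and 9.72 ± 3.71 FPKM in the same order), TJP1 (8.77 ± 2.53, 9.34 ± 1.39, 7.24 ± 0.678 and 8.38 ± 2.68) and CLDN1 (31.8 ± 1.95, 31.6 ± 0.835, 27.5 ± 2.29 and 29.3 ± 5.6) had adjusted p-values of at least 0.888 in each pairwise comparison. SQOR, which oxidises sulfide in mitochondria and is named SQRDL in the tables, measured 25.4 ± 1.86 FPKM in control, 17.1 ± 0.153 with NaHS, 22.3 ± 1.17 with LPS and 17.7 ± 0.509 with LPS+NaHS as a sum of isoforms (log2 -0.54, adjusted p = 0.0996 for NaHS, and -0.49, adjusted p = 0.0660 for LPS+NaHS against control). CXCL8 was at 0.367 to 1.61 FPKM and TLR4, the LPS receptor, at 0 to 0.0150 FPKM in the gene table. Both were below the filter there, so they were not tested with those gene values.

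There were 12 lists that passed in no comparison, and their smallest camera adjusted p-values were as follows. For LPS against control they were 0.0855 for the ATF4 amino acid response (median 0.11), 0.0855 for antigen presentation (0.23), 0.120 for Wnt target genes (-0.18) and 0.298 for tight and adherens junctions (-0.08). For LPS+NaHS against LPS they were 0.0570 for p53 targets and apoptosis (0.11), 0.107 for hydrogen sulfide production and oxidation (-0.24), 0.274 for LPS sensing and TLR signalling (-0.02) and 0.487 for metallothioneins (0.13). For LPS+NaHS against control they were 0.174 for TGF-beta response and extracellular matrix (0.05) and 0.191 for nuclear-encoded oxidative phosphorylation (0.03). The endoplasmic reticulum chaperones came closest with NaHS alone (-0.05, adjusted p = 0.0537), and DNA replication in the interaction (-0.05, adjusted p = 0.329). Mitochondrially encoded proteins and leukocyte and stromal markers had 1 measured gene each above the filter and were not tested as lists.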

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

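Among the tests in this part, the share of single-exon loci was chosen only after the result was seen. Each result below was taken up because the NaHS effect differed between cells with and without LPS in a test of that difference (the interaction).

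GSG2 (log2 interaction 2.44), MCFD2 (-1.67), TMEM167A (2.32) and GDF11 (-1.60) each took 1 of 2 separate levels, as did 217 of the loci tested, and in these 4 the levels followed the groups. Estimation that varies from library to library without regard to treatment may account for them, since 7.53% of the 15400 ways to part the libraries into trios gave at least 4 such loci (mean 1.64, highest other 8). Single-exon transcripts kept or lost by the assembly could account for part of the 217, as 47.0% of them have a single-exon leading isoform against 3.38% of other loci, a ratio of 13.9, but of the 4 only GSG2 has 1 exon. Reads moved between a locus and loci that overlap it do not account for most of the change, with a median of 0.0245 of the change in bases cancelled by the neighbours, though the share was 0.175 for GDF11. An effect of treatment on these 4 genes stays open, because the tests do not tell it from such estimation.

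PITHD1 had an interaction of 1.03, with 8.81 ± 0.336 FPKM in control, 9.52 ± 0.650 with NaHS, 3.75 ± 0.295 with LPS and 9.40 ± 0.622 with LPS+NaHS. Its values also lay at 2 levels that followed the groups, 3.42 to 3.99 FPKM with LPS and 8.50 to 10.1 FPKM elsewhere. It was not among the 217 loci, which needed a log2 gap of at least 1 between levels. Whether estimation accounts for PITHD1 was not tested.

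Lists with higher interaction terms were goblet and other secretory markers (median 0.38), immediate early genes (0.29), interferon-stimulated genes (0.27), aryl hydrocarbon receptor and xenobiotic metabolism (0.32), the heat shock response (0.14), NRF2 targets (0.0761) and histones with nuclear-retained RNAs (0.70). Lists with lower terms were hypoxia and glycolysis (-0.17), cholesterol biosynthesis (-0.17) and the mitotic cell cycle (-0.15).

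Other splits of the libraries were counted for the interaction with 100 splits. As many genes as the real 5 came from 6 splits, with 6 in the highest other, and as many isoforms as the real 3 from 43 splits, with 12 in the highest other, so chance is not excluded for either. For the lists, only 1 split, the real one, gave 10 with the preset correlation of 0.01, with 7 in the highest other. The splits mixed libraries with and without NaHS, so they remove any NaHS effect and not only a difference between the states. They therefore cannot exclude chance for the number of lists. With an estimated correlation 0 of these lists passed (camera), where 10 had passed with the preset one.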

How the results depend on the processing

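The GC correction, dropping the least similar library of each group, and symbol sums were chosen after seeing the data. Of the results with a direction, 1328 values of named genes and 319 of gene lists stayed on the same side of their threshold and of 0. Another 166 gene values and 91 list values lost their call, 37 gene values gained one, and 49 gene values and 1 list value changed sign. Effect correlations had no threshold, and all 39 values kept their sign and lay within a standard error of the main value. That standard error was computed from the fits with a library left out, which make up most of the 39. This outcome was therefore close to fixed in advance and does not show stability. Among counts, 121 stayed within 1.5 times and 75 did not. The reversed genes are HMOX1, NFKBIA, OCLN, TJP1 and CLDN1, none of which passed in any comparison. Aligned depth was 5.62 to 7.63 gigabases, and whether it limits genes near 1 FPKM was not tested. Isoforms were listed at 0 also where other libraries measured far more than 1 FPKM. The PMF1 isoform ENST00000368277 measured 32.4 to 44.6 FPKM with LPS and was listed at 0 in LPS+NaHS 1 and LPS+NaHS 2. Sample weights were estimated by an iteration that stopped before it converged. For changes with a setting the cause was not tested, except that a stricter filter or fewer libraries leave fewer genes or values in the fit.

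With log2(FPKM + 0.5), 7 genes passed for NaHS and 4 for LPS against control. Without a filter there were 8 for LPS, 25 for LPS+NaHS against LPS, 16 for LPS+NaHS against control and 12 for the interaction. A mean of at least 5 FPKM gave 4 for LPS, 16 for LPS+NaHS against control and 3 for the interaction, and 2, 3 and 8 isoforms for NaHS, LPS and LPS+NaHS against control. With log2(FPKM + 0.1), 3 isoforms passed for NaHS, 7 for LPS+NaHS against control and 6 for the interaction. TPM rescaling gave 2 genes for NaHS and 14 for LPS+NaHS against control, and the sum of isoform FPKM gave 4 for LPS, but the filter then let 15380 and 11633 genes through against 10431, so that scaling or summing changed together with the genes tested. Fits on only the groups compared gave 13, 5, 9 and 13 genes for NaHS, LPS, LPS+NaHS against LPS and LPS+NaHS against control. Of these, 2, 2, 4 and 7 were also called in the main fit. An estimated correlation left 1, 1, 0, 2 and 0 lists in the 5 comparisons, where the preset correlation had 5, 3, 5, 4 and 10. For NaHS against control the main split of 1 gene higher and 3 lower became 5 and 7 with the GC correction, 3 and 3 with the sum of isoforms, 10 and 3 with only the groups compared and 6 and 2 without control 2.

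Sample weights gave 73 genes for NaHS, 10 for LPS and 12 for LPS+NaHS against control. They turned OCLN (0.0553) and CLDN1 (0.0393) for NaHS, OCLN (0.23) and TJP1 (0.15) for LPS+NaHS against control, and HMOX1 (-0.0347) and NFKBIA (-0.0511) in the interaction. Dropping the least similar library of each group gave 21 genes for NaHS, 20 for LPS, 24 for LPS+NaHS against LPS and 21 for the interaction. Of these, 2, 2, 5 and 4 were also called in the main fit. This setting gave 2 lists each for NaHS, LPS+NaHS against LPS and LPS+NaHS against control. It turned OCLN (0.0515) and CLDN1 (0.0257) for NaHS, OCLN (0.15) for LPS, OCLN (0.45), TJP1 (0.38) and CLDN1 (0.0530) for LPS+NaHS against control, HMOX1 (-0.12) and NFKBIA (-0.0922) in the interaction, and the ribosomal list for LPS+NaHS against control (adjusted p = 0.311, range over alternatives 0.0289 to 0.581). The GC correction gave 12 genes for NaHS, 4 for LPS and 49 for LPS+NaHS against control, with 8 lists for NaHS and 5 for LPS, and turned CLDN1 for LPS+NaHS against LPS (-0.0312).

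With the replicate number as a block, 2, 8, 8 and 3 genes passed for NaHS, LPS+NaHS against LPS, LPS+NaHS against control and the interaction, and 1, 0, 6, 8 and 1 isoforms in the 5 comparisons, where limma without the block had 6, 6, 10, 13 and 3. For LPS the 0 isoforms stand beside 1215 at an unadjusted p under 0.05 without the block. The number of lists was unchanged in the 5 comparisons. Same-number libraries correlated at -0.175 to 0.309 after removal of group means, with 2 of 18 pairs over 0.1, both between control and LPS+NaHS (0.263 and 0.309, the third -0.0176), and 6 of 12 libraries matched best with a library of their own number, so the numbers do not show pairing.

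Leaving out 1 library at a time gave 3 to 8 genes for NaHS (8 without control 2 or NaHS 2, 7 without control 3), 3 to 9 for LPS (4 without control 1, 6 without control 2 or control 3, 9 without LPS 1, 5 without LPS 2), 9 to 142 for LPS+NaHS against LPS (9 without LPS 3, 142 without LPS+NaHS 1), 12 to 42 for LPS+NaHS against control (15 without control 1, 14 without control 2, 42 without LPS+NaHS 1, 12 without LPS+NaHS 3) and 4 to 8 for the interaction (8 without control 2, NaHS 2 or LPS 1). Lists ranged from 2 to 6 for NaHS (2 without control 2, 3 without NaHS 2), 2 to 6 for LPS (6 without LPS 2), 4 to 8 for LPS+NaHS against LPS (8 without LPS+NaHS 2), 2 to 7 for LPS+NaHS against control (7 without control 1, 2 without LPS+NaHS 3) and 5 to 11 for the interaction (5 without LPS+NaHS 3). Signs changed within these ranges of log2 fold change. For NaHS they were OCLN -0.26 to 0.26, TJP1 -0.0447 to 0.30 and CLDN1 -0.0424 to 0.0413. For LPS they were OCLN -0.42 to 0.0710 and NFKBIA -0.000528 to 0.18. For LPS+NaHS against LPS they were OCLN -0.13 to 0.38, TJP1 -0.0347 to 0.39 and CLDN1 -0.0594 to 0.21. For LPS+NaHS against control they were HMOX1 -0.14 to 0.0905, OCLN -0.37 to 0.19, TJP1 -0.25 to 0.18 and CLDN1 -0.26 to 0.00655. In the interaction they were HMOX1 -0.0760 to 0.15, NFKBIA -0.13 to 0.13, OCLN -0.13 to 0.43, TJP1 -0.16 to 0.29 and CLDN1 -0.0543 to 0.21.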

Other observations

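Tests chosen only after the result was seen in this part are the symbol sums, the GC correction and the share of the first component held by treatment. Isoform sums per gene symbol brought in genes that the gene table joins with others, and 1 member of the hydrogen sulfide list was lower with NaHS when adjusted over the list alone. That was SQRDL, the sulfide oxidising enzyme, at 25.4 ± 1.86 FPKM in control and 17.1 ± 0.153 with NaHS (log2 -0.54, limma adjusted p = 0.000975 over the list alone). With symbol sums the list of hydrogen sulfide production and oxidation fell, with 3 of 12 members above 0 and a median of -0.26 (camera adjusted p = 0.00398), whereas the planned test on the gene table did not pass (2 of 8 above 0, median -0.19, mean 0.02, adjusted p = 0.360, and adjusted p = 0.622 with an estimated correlation). AHCY, which frees homocysteine, measured 465 ± 58.6 and 339 ± 53.8 FPKM, and the methanethiol oxidase gene SELENBP1 30.5 ± 4.12 and 24.1 ± 3.36. Cholesterol biosynthesis rose with NaHS (19 of 21 above 0, median 0.15, adjusted p = 0.0102), where the planned test had an adjusted p of 0.0515 (0.286 with an estimated correlation), with MSMO1 at 33.4 ± 11 and 60.7 ± 4.68 FPKM. No member of either list passed over all genes, and an estimated correlation was not used with symbol sums.

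After LPS, Wnt target genes fell with symbol sums (3 of 14 above 0, median -0.23, adjusted p = 0.00653), where the planned test had 0.120. None passed over all genes, and 4 were lower when adjusted over the list alone: the Wnt antagonist DKK1 (53.6 ± 5.42 in control and 30.5 ± 1.6 FPKM with LPS), the feedback inhibitor AXIN2 (8.42 ± 0.715 and 5.03 ± 0.706), ZNRF3 (log2 -0.28) and NKD1 (log2 -0.39). Antigen presentation rose (8 of 9 above 0, median 0.27, adjusted p = 0.0124, planned test 0.0855), with HLA-C at 60.4 ± 17.2 and 79.3 ± 5.54 FPKM, but no member passed over all genes or over the list alone (smallest adjusted p = 0.298 over the list, limma). Between LPS and LPS+NaHS, p53 targets rose (13 of 17 above 0, median 0.12, adjusted p = 0.0420, planned test 0.0570), with the survival gene BCL2L1, alone higher when adjusted over the list, at 120 ± 2.67 and 171 ± 20.4 FPKM. Symbol sums also gave calls for the aryl hydrocarbon receptor list in LPS+NaHS against LPS (adjusted p = 0.0311, planned 0.0904), the goblet (0.0448, planned 0.0502) and immediate early (0.0461, planned 0.0536) lists in LPS+NaHS against control, and the enterocyte list in the interaction (0.0151, planned 0.0723). They ended 5 calls: mitotic (adjusted p = 0.0689) and fatty acid oxidation (0.114) for NaHS, ribosomal for LPS (0.0655), goblet for LPS+NaHS against LPS (0.0513) and histones with nuclear-retained RNAs in the interaction (0.0569).

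The first principal component parted libraries within groups. GC content may account for it, since gene weights correlated with GC at r = -0.652. A first component computed anew after the GC correction held 14.5% of the variance, against 21.3% before. The correction removes GC trends by construction, so this drop is no separate evidence for GC content. Transcript length left the matter open (r = 0.265). Treatment held 0.256 of the component's variance (exact permutation p = 0.459), which gives no sign of a treatment effect on it.

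The higher NRF2 list in LPS+NaHS than in LPS was weighed against 3 technical explanations. Reads traded between AKR1C paralogs would cancel in a sum, but the sum of 3 AKR1C genes went from 70.0 ± 4.54 to 215 ± 45.9 FPKM (log2 1.58). Without aldo-keto reductases the set test of the other 15 members gave an unadjusted p = 1.36e-05 (p = 0.0191 with an estimated correlation). All 16 members gave an unadjusted p = 1.25e-07 (p = 0.0114 with an estimated correlation) in the same test, so the list was weaker without the reductases. After the GC correction the median was 0.23 against 0.30 before. A response of NRF2 targets to NaHS in LPS cells may account for the list, as a hypothesis found and tested on the same data, and with all members an estimated correlation gave an adjusted p of 0.0987 (range over alternatives 7.65e-09 to 0.0987).

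Bases moved between isoforms of the same locus could account for part of the isoforms that passed in genes that did not, and the share of the change cancelled by other isoforms had a median of 0.302, which does not settle it.

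For comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. Genes were 4 for NaHS (highest other split 3), 2 for LPS (4), 14 for LPS+NaHS against LPS (2) and 26 for LPS+NaHS against control (585), so that 1, 5, 1 and 2 splits gave as many. Isoforms were 6 (highest other 9), 6 (12), 10 (8) and 13 (13) in that order, with 2, 4, 1 and 2 splits, and lists 5 (3), 3 (2), 5 (3) and 4 (7), with 1, 1, 1 and 2 splits. The split with 585 genes set control 1, control 3 and LPS+NaHS 1 against control 2, LPS+NaHS 2 and LPS+NaHS 3, which points to a structure of the samples and follows their GC trend.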
